A study of Strongylocentrotus purpuratus with 191 samples.

How the data were processed

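Gastrula-stage embryos of the purple sea urchin Strongylocentrotus purpuratus were profiled with a custom panel of the Illumina DASL assay, in which pairs of short oligonucleotides are extended and ligated on cDNA, amplified with labelled primers and read on a bead array. Total RNA was taken from 191 cultures, per the labels. The cultures came from 32 crosses between 8 females and 8 males, each grown at 12C, 15C and 18C in 2 replicates, and 1 cross-by-temperature combination had 1 culture. The parents formed 2 blocks, named 3 and 4 in the labels, and within each block every female was mated to every male, giving 16 crosses. Parents are named by a letter and their block, and a female and a male can carry the same name (female A3 and male A3 are different animals). Block 3 was assayed on 1 plate and block 4 on the other, so block and plate cannot be told apart. Plate rows nearly followed temperature. The labels also gave a sampling time, for which no unit was stated, and the mean and SD of a culture stage score, whose scale was not stated.

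The authors' normalized values are on a log2 scale and centred on 0 for each probe within a plate, with the centring read from the values and the normalization method not given in the sources used here. BeadStudio is named in the submitters' processing notes. A deposited table of non-normalized values ran from 7.18 to 14.7, a range that was read as log2 intensity. On each plate the normalized values rose with the array-centred non-normalized ones with slopes of 0.835 and 0.844, so differences on the normalized scale are smaller than on the non-normalized scale. The value table of the series matrix held the same numbers as the normalized table (largest difference 0) and gave no separate alternative. The normalized table held 336 probes of 74 genes, with 2 to 6 probes per gene. The non-normalized table held 384 gene probes of 77 genes, 27 negative controls and 17 other controls. Of its array columns, 1 was marked as of poor quality, was mapped to no sample and was not used. The files give no detection p, so the planned filter on undetected probes could not be applied and all 74 genes were tested. Detection was instead set against the negative controls (a probe was detected where under 0.05 of the negative controls of its array reached its value) for alternatives chosen after seeing the data. Of the gene names on the panel, 28 matched a symbol or synonym of the reference gene table, and all genes keep the names of the files.

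A gene's value was the mean of the log2 values of its probes. The median panel signal before normalization was 9.90 ± 0.339 (log2, SD, n = 96) in block 3 and 12.2 ± 0.155 (SD, n = 95) in block 4, and 83.8% and 83.9% of probe values were detected. In block 3 this signal differed between temperatures: 9.67 ± 0.280 at 12C, 9.97 ± 0.299 at 15C and 10.0 ± 0.322 at 18C (SD, n = 32 each). In block 4 it averaged 12.2 at each temperature. Of the genes, 9 lay less than 1 log2 unit above the negative controls in block 3 and 5 in block 4. For an array the number of cultures limits the precision. The median SD between 2 replicates was 0.19 on the log2 scale over genes. No 2 arrays held identical values, and the highest correlation between 2 arrays was 0.910. The labels call the cultures replicates of a cross. Whether these were separate fertilizations was not stated, so the temperature and parent tests used means over replicates.

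Temperature was tested with limma on 96 cross-by-temperature means with the cross as a fixed block (62 residual df), for 18C against 12C, 15C against 12C, 18C against 15C and the departure of 15C from the mean of the other 2 temperatures. The difference in temperature response between blocks was a moderated F test on 2 df of the same means. Dam and sire effects were moderated F tests on 6 df over 32 cross means, with the dam-by-sire scatter as residual (18 df). Dam by temperature and sire by temperature were moderated F tests on 12 df over the 96 means (36 residual df). The slope on culture stage used all 191 cultures, with cross and temperature in the model. All p-values from limma were adjusted with the Benjamini-Hochberg method over 74 genes, with a threshold of 0.05. Culture stage itself was compared with two-sided permutation tests that exchanged temperatures within crosses, or exchanged one sex of parent within block, other parent and temperature (an F statistic), with 100000 resamples, and adjusted over 5 tests. Gene lists were tested with camera (preset correlation of 0.01, and an estimated correlation) and fry, for lists with at least 3 measured genes. Shares of variance were estimated by REML with lme4 from all cultures. R 4.3.3, limma 3.58.1, lme4 1.1.37, python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

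The tests, the 12 gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. Named genes were up to 10 highest and 10 lowest changes past the threshold for 18C against 12C with the same sign in both blocks, every measured heat shock gene, the 5 smallest p past the threshold for the departure, temperature by block, dam, sire and each parent-by-temperature test, up to 5 slopes on stage per direction, and 2 members of each list that passed a test. Same-numbered replicates did not deviate together, and the numbers were not used as pairs. Alternatives covered the other deposited table with 2 normalizations (normexp background correction with an offset of 50 and quantile normalization, or arrays centred on their medians), single probes, medians of probes, single cultures, covariates for stage, sampling time and plate position, single blocks, single replicates, single parents left out, a replicate block, arrays centred on their medians, arrays of distant medians left out and 2 detection filters.

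The fits were tested on simulated values for 74 genes, drawn with the SD between replicates of each gene, in 20 rounds. The values were drawn independently for each gene and culture. They held no correlation between genes, no array-wide level and no further scatter between crosses, so the shares recovered may be too high for the real data. Of planted 18C-against-12C changes, 95% were recovered at a log2 size of 0.2 and 61% at 0.1. For a log2 difference of 0.2 between parents, 89% of planted dam effects and 84% of planted sire effects were recovered. Of planted temperature-by-block differences of 0.2, 53% were recovered, and of planted dam-by-temperature effects of 0.2, 20%. A slope of 1 log2 unit per unit of stage was recovered in 67% of planted genes.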

Results

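Expression of 74 genes of the sea urchin developmental gene network was measured in gastrula embryos of 32 crosses raised at 12C (64 cultures), 15C (63 cultures) and 18C (64 cultures). Sampling times averaged 37.5, 28.4 and 23.1 at the 3 temperatures, in a unit that the labels do not state. The series title gives the question as the genetics of expression responses to temperature stress, and the factorial crosses separate the temperature at which embryos grew from the contributions of mothers (dams) and fathers (sires). All changes below are on the log2 scale of the authors' normalized values, ± SE unless stated.

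In embryos grown at 18C, 8 genes were higher than at 12C and 5 were lower, and no gene list passed a test. Dkk, encoding a secreted antagonist of Wnt signalling, was higher by 0.38 ± 0.09 and in 24 of 32 crosses. brn1-2-4, a POU-domain transcription factor gene of the embryonic gut, was higher by 0.32 ± 0.05 and in 29 of 32 crosses. nodal, the ligand that specifies the oral side, was higher by 0.13 ± 0.03, its antagonist Lefty by 0.12 ± 0.04 and BMP2-4, a ligand that Nodal signalling activates, by 0.12 ± 0.04. FoxB, a forkhead transcription factor gene, fell by 0.19 ± 0.05 and was lower in 23 of 32 crosses. Its change was -0.05 ± 0.06 in block 3 and -0.32 ± 0.08 in block 4. C-lectin, a C-type lectin gene, fell by 0.17 ± 0.04 and was lower in 22 of 32 crosses.

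In all, 13 of 74 genes passed an adjusted p of 0.05 for 18C against 12C in limma, with adjusted p from 4.51e-07 for brn1-2-4 to 0.0342 for BMP2-4. The other higher genes were Gelsolin, an actin-severing protein gene (0.24 ± 0.07), SpColl-ColAlpha, a collagen chain gene (0.17 ± 0.05), and Mitf, a bHLH transcription factor gene (0.09 ± 0.03). The other lower genes were Erg, an ETS transcription factor gene (fell by 0.15 ± 0.04), cyclophilin, a peptidyl-prolyl isomerase gene (fell by 0.10 ± 0.02), and Su(H), the transcription factor of Notch signalling (fell by 0.08 ± 0.03, lower in 19 of 32 crosses). Dkk, read by 2 probes, lay 1.01 log2 units above the negative controls in block 3. Probes disagreed in sign for SpColl-ColAlpha (3 of 4 probes higher), Lefty (3 of 5 higher) and Erg (3 of 4 lower). With only the brightest probe, the changes of SpColl-ColAlpha and Lefty turned to -0.00497 and -0.0215. All 13 genes had the same sign in block 3 and in block 4, which their selection on the mean over both blocks favours. The blocks tested singly called 4 and 8 genes, and only 1 gene, brn1-2-4, was called in both. Of the 13 genes, 4 were also called for a temperature response that differed between blocks. The calls numbered 24 (11 higher, 13 lower) and 29 (10 higher, 19 lower) in the non-normalized table under 2 normalizations, 21 with array medians or plate column means removed, 7 with culture stage as a covariate, with the median of probes or without the cross as a block, 6 without replicate 1 and 5 without replicate 2.

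**Figure D1:**
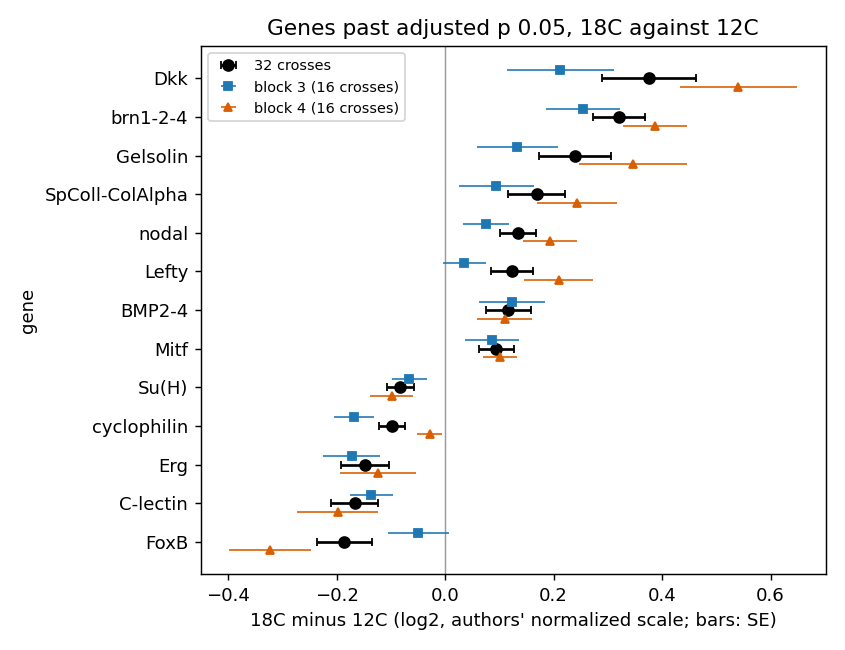
Change from 12C to 18C (log2, horizontal axis, bars are SE) for the 13 genes past the threshold, over 32 crosses (circles) and within block 3 (squares) and block 4 (triangles). Every gene lies on the same side of 0 in both blocks, from Dkk at 0.38 to FoxB at -0.19 over all crosses. Selection on the change over both blocks favours such a shared side.

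By list, the 25 skeletogenic mesenchyme genes gave 1 higher (Mitf) and 4 lower (FoxB, C-lectin, Erg, cyclophilin), and 5 when adjusted over the list alone. Of 13 endoderm genes, brn1-2-4 and Gelsolin rose and none fell, and the count was also 2 adjusted over the list alone. Of 12 oral ectoderm genes, nodal, Lefty and BMP2-4 rose and none fell, and the count was 3 adjusted over the list alone. Of 13 signalling genes, nodal, Lefty and BMP2-4 rose and Su(H) fell, with 5 adjusted over the list alone. The 4 genes of non-skeletogenic mesoderm and pigment cells gave 1 lower gene, Erg, and 3 adjusted over the list alone, and the 4 aboral ectoderm genes gave 0 by either adjustment (limma, all 4 changes below 0, the gene-wise median -0.01). Dkk and SpColl-ColAlpha belonged to no list. No list moved as a whole against the rest of the panel (camera adjusted p = 0.292 for each of the 6 lists, adjusted p = 0.606 with an estimated correlation), and the smallest fry adjusted p was 0.314. The skeletogenic list had a median of 0.01 and a mean of -0.00413, which differ in sign. Lists for the ciliary band and apical domain, maternal regulators, housekeeping, cell cycle, heat shock and chaperones, and stress defence had fewer than 3 measured genes and were not tested, and no heat shock gene was measured.

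At 15C, brn1-2-4 (0.17 ± 0.05, higher in 25 of 32 crosses) and Dkk (0.30 ± 0.09, higher in 24) were higher than at 12C, and FoxB fell by 0.17 ± 0.05 (lower in 26). These 3 genes were the only ones past the threshold for 15C against 12C, with limma adjusted p of 0.0316, 0.0316 and 0.0389. The rises were larger in block 4: brn1-2-4 changed by 0.05 ± 0.07 in block 3 and 0.30 ± 0.06 in block 4, without passing the test of a difference between blocks (F = 3.67, adjusted p = 0.134), and Dkk by -0.07 ± 0.10 and 0.67 ± 0.11, while FoxB changed by -0.16 and -0.17. Across genes, the 15C changes in the 2 blocks had a Pearson r of 0.143 and a Spearman rho of 0.131, against 0.733 and 0.684 for 18C against 12C, and genes are not independent replicates. Only 19 of 74 genes had the same sign in both blocks for 15C against 12C, and 54 did for 18C against 12C. At 15C the panel shifted apart between blocks (median change -0.04 with 14 genes higher in block 3, 0.05 with 67 higher in block 4), and unrelated signs at these counts would agree for 18.4 genes, against 38.3 at the 18C counts. The count was 0 with the brightest probe, with stage as a covariate, without the cross as a block, without replicate 2 and in block 3 alone, 1 with probes detected on both plates, 5 in block 4 alone and 7 in the array-centred non-normalized table.

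Between 15C and 18C, SpColl-ColAlpha rose by 0.18 ± 0.05 (higher in 23 of 32 crosses), while C-lectin fell by 0.15 ± 0.04 (lower in 25) and Su(H) fell by 0.09 ± 0.03 (lower in 24). Each had a limma adjusted p of 0.0303 and no other gene passed. The count was 10 with array medians or plate column means removed and 0 in the array-centred non-normalized table, without the cross as a block, without replicate 2 and in block 3 alone. Without replicate 1 it was 1. No gene passed limma's test for a departure of 15C from a straight line over temperature (0 of 74), and 4 had an unadjusted p under 0.05. At an adjusted p of 0.05, the departure was called for 12 genes in block 4 alone and for 0 in block 3 alone (limma), where 22 and 17 had an unadjusted p under 0.05. The blocks ran in opposite directions, with a median departure of 0.0529 and 64 genes above 0 in block 4 and of -0.0523 and 13 genes above 0 in block 3, so the test over both blocks averages opposite shifts.

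The temperature response differed between the 2 blocks for 12 genes. The smallest p were those of Otp, an ectodermal homeobox gene (F = 12.7, adjusted p = 0.00120), Dkk (F = 12.2, adjusted p = 0.00120), notch, the Delta receptor gene (F = 10.6, adjusted p = 0.00259), cyclophilin (F = 9.80, adjusted p = 0.00349) and Not, a homeobox gene of the oral ectoderm (F = 9.48, adjusted p = 0.00349), all from limma. From 12C to 15C, Otp changed by -0.08 in block 3 and 0.09 in block 4. From 12C to 18C, cyclophilin changed by -0.17 ± 0.04 in block 3 and -0.03 ± 0.02 in block 4. Otp, notch and Not lay only 0.00, 0.10 and 0.06 log2 units above the negative controls in block 3. In block 4 they lay at -0.05, 0.57 and -0.06 log2 units relative to these controls. No probe of Otp or Not was detected in most cultures on either plate, and of the 6 notch probes 1 was, in block 4 only. The calls of these genes rest on signal near the negative controls. The count was 2 with array medians removed, 1 and 2 in the non-normalized table under 2 normalizations, 6 with either detection filter, 0 without replicate 1 and 5 without replicate 2.

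Mothers differed in the expression of 60 of 74 genes in their offspring. For most of the 74 genes the lowest dam in block 3 was female D3 and the highest dam in block 4 was female B4. The 60 calls are therefore not independent results for single genes. Erg had the largest F (F = 27.6, adjusted p = 1.69e-07): offspring of female B3 stood 0.30 ± 0.14 (SD, n = 4 crosses) above their block mean and those of D3 at -0.26 ± 0.10, a range of 1.47-fold. FoxO (1.55-fold, block 4), gcm (1.51-fold, block 3) and frizzled9 (1.48-fold, block 4) ranged wider between dams (named after their values were seen). Bra, a T-box gene of the gut and oral ectoderm, Wnt8, an early signal of the vegetal embryo, nodal, and snail, a zinc-finger transcription factor gene of migrating mesenchyme, followed Erg by p in limma, with adjusted p of 8.71e-07, 4.11e-06, 6.95e-06 and 6.95e-06. Offspring of female B4 were highest in block 4 for Bra and Wnt8 and 1.25-fold and 1.28-fold above the lowest female, A4. snail lay 0.39 log2 units above the negative controls in block 3. ficolin and Otp, also called (limma adjusted p = 0.00804 and 0.0431), had no probe detected in most cultures on either plate. Their calls rest on signal near the negative controls. Over the called genes, the median range between the highest and the lowest dam was 1.12-fold in block 3 and 1.15-fold in block 4. The count was 49 with array medians removed, 27 in block 3 alone, 25 without replicate 1 and 35 without replicate 2.

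Fathers differed in the expression of 56 of 74 genes. For most of the 74 genes the highest sire was male C3 in block 3 and male D4 in block 4. The 56 calls are therefore not independent results for single genes. tbr, a T-box gene of the skeletogenic mesenchyme, had the largest F (F = 27.1, adjusted p = 2.03e-07): offspring of male D4 stood 0.26 ± 0.10 (SD, n = 4 crosses) above their block mean and those of male A4 at -0.27 ± 0.22, a range of 1.44-fold. gcm (1.47-fold, block 3) and gataC (1.46-fold, block 4) ranged wider between sires (named after their values were seen). Pmar1, a homeobox repressor at the top of the skeletogenic programme, ranged 1.40-fold in block 3 and 1.41-fold in block 4 (adjusted p = 2.80e-05). FoxB (adjusted p = 2.92e-05), SM30-E, a spicule matrix protein gene (adjusted p = 3.27e-05), and Tel, an ETS transcription factor gene (adjusted p = 7.72e-05), followed in limma. The median range between sires was 1.13-fold in block 3 and 1.14-fold in block 4. Alx1, ficolin and Not were also called (limma adjusted p = 0.00436, 0.000428 and 0.0397). No probe of these genes was detected in most cultures on either plate, so their calls rest on signal near the negative controls. The count was 38 with array medians removed, 34 and 24 in the non-normalized table under 2 normalizations, 29 without the 10 arrays of most distant median, 34 in block 3 alone and 26 in block 4 alone, 47 without replicate 1 and 10 without replicate 2. tbr, Pmar1 and SM30-E passed the sire test under each of the 31 alternatives run.

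**Figure D2:**
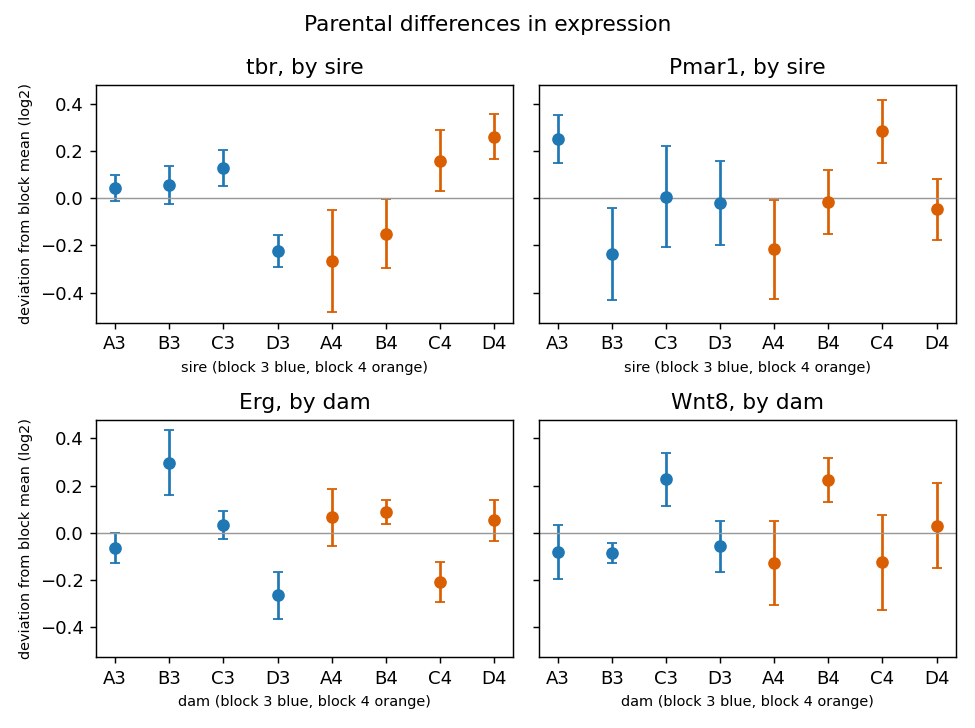
Deviation from the block mean (log2, vertical axis) of the offspring of each parent, as the mean of 4 crosses with bars of 1 SD, for 2 genes with a sire effect (tbr, Pmar1) and 2 with a dam effect (Erg, Wnt8). Blue marks block 3 and orange block 4, and tbr runs from -0.27 for male A4 to 0.26 for male D4.

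Both parents were called for 46 genes, the dam only for 14, the sire only for 10 and neither for 4 (Gelsolin, Lhx2, notch and VEGF-3, named because the count was small). Independent lists of these lengths would share 45.4 genes. Of the skeletogenic mesenchyme list, 23 of 25 genes had a dam effect and 19 a sire effect, of the endoderm list 10 and 11 of 13, and of the oral ectoderm list 9 and 10 of 12. These counts stayed the same when adjusted over the list alone. In the variance model, dams took a median of 10.3% of the variance left after temperature and block and sires 7.94%, while differences between cultures of 1 combination took 69.8%. With array medians removed, the medians were 7.77% for dams and 4.74% for sires. For tbr, sires took 58.8%, the highest share of any gene, and for Pmar1 35.1%.

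No gene showed a dam-by-temperature or a sire-by-temperature effect past the threshold (0 of 74 in each limma test), and 7 and 2 genes had an unadjusted p under 0.05. The smallest adjusted p were 0.439 and 0.499. Lhx2, a LIM homeobox gene, had the smallest dam-by-temperature p (named after its values were seen) and lay 0.31 log2 units above the negative controls in block 3. The median shares of variance were 1.18% for dam by temperature and 0% for sire by temperature, and 0.162% and 0% with array medians removed. As 20% of simulated dam-by-temperature effects of 0.2 were recovered, effects of that size would mostly not have been detectable with these cultures.

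Culture stage scores averaged 0.328 ± 0.0488 at 12C, 0.359 ± 0.0827 at 15C and 0.358 ± 0.0739 at 18C (SD, n = 32 crosses). The score was higher at 18C than at 12C by 0.0299 in 26 of 32 crosses (permutation p = 0.0113, adjusted p = 0.0188) and higher at 15C than at 12C by 0.0309 in 23 crosses (permutation p = 0.00877, adjusted p = 0.0188). The SD between 2 replicates of a combination was 0.0530. In block 3 the 18C difference was 0.00834 (permutation p = 0.613) and in block 4 it was 0.0515 (permutation p = 0.00189). Offspring of female D4 averaged 0.463 ± 0.0571 and those of female C3 0.283 ± 0.0412 (SD over 12 combinations of male and temperature). Dams took 68.2% of the stage variance left after block, temperature and sire (permutation p = 1e-05, the smallest that the resamples can give, adjusted p = 5e-05), and sires 11.2% of that left after block, temperature and dam (permutation p = 0.0504, adjusted p = 0.0630).

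**Figure D3:**
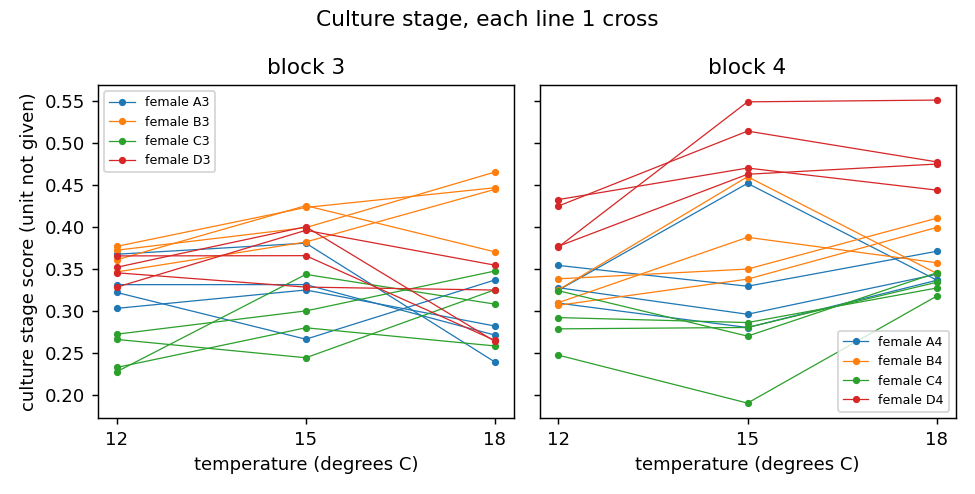
Culture stage score (vertical axis, unit not given) against temperature (degrees C) for each of 32 crosses, with 1 line per cross coloured by female, block 3 left and block 4 right. In block 4 the 4 crosses of female D4 lie at the top, with a mean of 0.463 over temperatures.

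deadringer, an ARID-domain transcription factor gene, was the 1 gene whose expression followed culture stage with cross and temperature in the model. It rose by 0.10 ± 0.02 log2 per 0.1 unit of stage score (limma adjusted p = 0.00132, 191 cultures). The slope per unit of score was 0.92 in block 3 and 1.04 in block 4. frizzled9, brn1-2-4, CyclinT and Hnf6 shared the next adjusted p of 0.0930 (named after their values were seen). The call was lost with sampling time as a covariate, with plate column means removed, in block 3 alone and without either replicate, with a count of 0 each, and with the brightest probe, where 1 other gene passed, and comparing only the 2 replicates of a combination called 6 genes. None of the 6 lists followed stage (camera adjusted p = 0.663 for each, adjusted p = 0.844 with an estimated correlation).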

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

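In this part, the tests of near-background signal and of array level for the block difference were chosen after the result was seen. A difference between groups marked the 12 genes whose temperature response differed between blocks. The difference between blocks in the change from 12C to 15C (block 4 minus block 3) was 0.17 for Otp, 0.74 for Dkk, 0.18 for notch, 0.18 for cyclophilin, 0.13 for Not, 0.20 for Ets1, 0.10 for Mif-7, 0.11 for soxb1, 0.19 for Mitf, 0.13 for Lim1, 0.11 for Msp130 and -0.0110 for FoxB. FoxB differed instead at 18C, by -0.27.

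The 15C shift ran over most of the panel: the median change from 12C to 15C was -0.04 in block 3, with 14 of 74 genes higher, and 0.05 in block 4, with 67 higher. Removing each array's panel median left 2 of the 12 calls, Dkk and cyclophilin (largest adjusted p 0.00328), which argues against an array-wide level as the whole cause for those 2. The 15C difference of Dkk went from 0.739 to 0.632, but that of cyclophilin fell from 0.181 to 0.0743, so an array-wide level stays open for the part removed, while its 18C difference stayed (0.139 ± 0.0437 before, 0.141 ± 0.0297 after). For the 8 other genes that differ most at 15C, a median of 0.266 of the 15C difference remained, as an array-wide level would give. These 8 genes were grouped by losing their call on the same removal, which favours a small share. Ets1 and Mitf nevertheless kept differences of 2.30 and 2.61 SE. A response of the whole panel in 1 set of parents would be removed alike and stays open. FoxB and Lim1 differ most at 18C, where the panel medians of both blocks were 0.01 and a median of 0.994 of the difference remained, so an array-wide level does not account for their 18C differences. FoxB went from -0.273 ± 0.0941 to -0.272 ± 0.0825 with an unadjusted p of 0.00790 before and 0.00744 after, and its call ended only in the adjustment over genes. Lim1 went from -0.140 ± 0.0753 to -0.139 ± 0.0584 at 18C, and its call ended as its 15C difference fell from 0.13 to 0.02. Signal near background applied to 4 of the 12 genes (33.3%, against 9 of 74 on the panel) and stays open for these. Only 2 of 100 splits of the crosses into blocks, the real one included, gave as many genes as the real 12, but the highest other split gave 36, which points to a structure of the samples or to the correlation among genes, not tested apart. Block equals plate, so a difference between the 2 sets of parents cannot be told apart from the plate.

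A dam effect in 60 genes and a sire effect in 56 invite technical explanations. A sequence variant under a single probe would leave that probe unrelated to the others of its gene. Dam deviations correlated more within genes than between them by 0.304 (95% bootstrap 0.249 to 0.357). As a median over the probe pairs of all called genes, this leaves variants open behind single dam calls. The genes were also called on the mean of their probes, which favours probes that agree. For sires the gap was 0.195 (0.134 to 0.246) and variants stay open. Plate column does not account for the effects, since 91.7% of dam and 92.9% of sire calls remained without it. Chance is unlikely for both, as 1 of 100 splits (the real one) reached the real count, with highest other counts of 11 and 27. Removing array medians kept 76.7% of dam and 62.5% of sire calls, so an array-wide level stays open for the rest. Culture stage as a covariate kept 78.3% of dam calls, which leaves stage open because dams differ in it. It kept 85.7% of sire calls, past the bound fixed beforehand, which argues against stage for the sire calls kept.

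For 18C against 12C, a straight drift over plate rows within temperatures predicted a median of 0.0505 of the observed change of the 13 genes. Its 95% bootstrap interval (-0.0823 to 0.431) lay below the share that such a drift would need as the main source. Plate rows nearly followed temperature, so a step between plate regions would look like temperature. This test cannot see such a step, which stays open. With culture stage as a covariate 53.8% of the calls remained (7 of 13), and the changes kept a median of 0.933 of their size (0.754 to 1.11) while their SE grew by a median factor of 1.06. Among the 6 lost ones, Gelsolin went from 0.24 ± 0.07 to 0.18 ± 0.07, SpColl-ColAlpha from 0.17 ± 0.05 to 0.13 ± 0.05 and Lefty from 0.12 ± 0.04 to 0.10 ± 0.04, so these calls ended as the changes shrank, and stage stays open for them. BMP2-4 (0.117 ± 0.0411 to 0.116 ± 0.0437) and Mitf (0.0944 ± 0.0323 to 0.0946 ± 0.0343) kept 0.998 and 1.00 of their change. The calls of these 2 genes ended with an SE about 1.06 times as large, which gives stage no support. Su(H) (-0.0823 ± 0.0254 to -0.0759 ± 0.0269) kept 0.922 of its change and its SE grew by a factor of 1.06. Both moved its call, so stage stays open for Su(H) too. The share of calls kept lies between the bounds fixed for this test, so it decides neither way for the 13 genes as a set. Chance is unlikely for the count of 13 (highest other split 8, 1 of 100 splits as large, the real one). The same holds for 3 for 15C against 12C (highest other 1, 1 of 100) and 3 for 18C against 15C (highest other 0, 1 of 100). These splits exchanged temperatures within each cross as if crosses were independent, although crosses share parents, so chance is not excluded.

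Chance cannot be excluded for the genes at an unadjusted p under 0.05 in the tests without calls: 29 of 100 splits gave at least the 4 genes for the departure from a line (highest other 27), 24 gave at least the 7 for dam by temperature (highest other 33) and 69 at least the 2 for sire by temperature (highest other 35). The highest counts, several times the real ones, point to a structure of the samples or to the correlation among genes, not tested apart.

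A signal also appeared in data outside the comparisons. The non-normalized table held 48 probes that are absent from the normalized one, of which 38 were detected against the negative controls in most cultures on each plate. They include all probes of Hmx, Kakapo and RBM8A, which lay 4.54, 3.87 and 5.41 log2 units above the negative controls in block 4 and 2.63, 2.41 and 3.89 in block 3.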

How the results depend on the processing

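Alternatives chosen only after seeing the data were the centring of arrays on their medians, the 2 detection filters, the median of probes and leaving out the 10 arrays of most distant median. Of 855 values of named genes under the alternatives, 696 kept their direction and their side of the threshold, 157 lost the call and 2 reversed. The reversed values were the 18C-against-12C changes of SpColl-ColAlpha (-0.00497) and Lefty (-0.0215) with the brightest probe, whose probes disagree. Erg, Bra, Wnt8 and nodal kept the dam call and tbr, Pmar1 and SM30-E the sire call in all 31 alternatives run for each, while for 18C against 12C the calls kept ran from 35 of 37 for brn1-2-4 to 18 for Mitf and 14 for BMP2-4. deadringer kept its stage slope call in 9 of 15, and with the brightest probe 1 other gene passed in its place. With array medians removed, the median variance share went from 10.3% to 7.77% for dams, from 7.94% to 4.74% for sires and from 1.18% to 0.162% for dam by temperature. Except where a sentence says otherwise, the cause was not tested.

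The 13 genes for 18C against 12C became 24 with normexp and quantile normalization of the non-normalized table and 29 with its arrays centred, 21 with array medians removed and 21 with plate column means removed, 7 with culture stage as a covariate, 7 with the median of probes and 7 without the cross as a block. Exact sign flips over the 8 females or the 8 males called 0 genes. The smallest p that these flips allow survives the adjustment only where many genes reach it together, and 15 and 24 genes had an unadjusted p under 0.05. The 3 genes for 15C against 12C became 7 in the array-centred non-normalized table, 1 with probes detected on both plates, and 0 with the brightest probe, without the cross as a block or with culture stage as a covariate. The 3 for 18C against 15C became 10 with array medians or plate column means removed, 5 with cultures singly, with plate row as a random block or with either detection filter, and 0 in the array-centred non-normalized table or without the cross as a block. The departure from a line went from 0 to 1 gene with plate column means removed. Dam by temperature went from 0 to 1 gene with cultures singly and to 1 in the array-centred non-normalized table.

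The 12 genes for temperature by block became 2 with array medians removed, 1 and 2 in the non-normalized table (normexp and quantile, array centred) and 6 with either detection filter. The 56 sire genes became 34 and 24 in the non-normalized table (normexp and quantile, array centred) and 29 without the 10 distant arrays. The stage slope called 0 genes with plate column means removed or sampling time as a covariate, 2 with either detection filter and 6 when only the 2 replicates of a combination were compared.

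Block 3 alone called 4 genes for 18C against 12C, 0 for 15C against 12C, 0 for 18C against 15C, 27 for dams, 34 for sires and 0 for the stage slope, and block 4 alone 8, 5 and 7 for the same temperature contrasts, 12 for the departure and 26 for sires, from fewer crosses. In block 3 the stage score differed by 0.00834 for 18C against 12C and 0.0263 for 15C against 12C, neither past 0.05, and in block 4 the 18C-against-15C difference, -0.00100 over all crosses, reversed to 0.0160. Leaving out replicate 1 or replicate 2, which takes away cultures, gave 5 to 6 genes for 18C against 12C, 0 to 3 for 15C against 12C, 0 to 1 for 18C against 15C, 0 to 1 for the departure, 0 to 5 for temperature by block, 25 to 35 for dams, 10 to 47 for sires and 0 to 0 for the stage slope. The same left-out replicates gave stage differences of 0.0278 to 0.0314 for 18C against 12C, 0.0258 to 0.0395 for 15C against 12C and -0.0117 to 0.00562 for 18C against 15C, which reversed without replicate 2, and sire shares of stage of 2.92% to 12.1%. The sire p for stage lay within resampling error of 0.05 over all cultures and without replicate 2. Leaving out 1 parent at a time gave 5 (without female A4) to 15 genes for 18C against 12C, 0 to 3 for 15C against 12C, 0 to 4 for 18C against 15C, 45 to 67 for dams and 33 (without female C3) to 57 for sires.

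With a replicate block (cross and replicate number together, cultures singly) the counts were 13, 3 and 5 for the 3 temperature contrasts and 0 for the departure. Cultures singly without that block also gave 5 for 18C against 15C, so the block itself changed no count. Deviations of same-numbered replicates had a median correlation of -0.00260, and 35 of 94 correlations were above 0.1. Signal over background limits the genes near the negative controls, 9 in block 3 and 5 in block 4.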

Other observations

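The tests in this part were fixed before their results were seen, with any p of 0.05 or more, or an interval that holds 0, to count against the hypothesis. Reading such a value as undecided was chosen after the values were seen. Levels of genes in offspring of different crosses moved together over much of the panel, with a median correlation of 0.388 over all gene pairs across 32 crosses after block means were removed, and 33.9% of the variance between cultures lay on 1 principal component. An array-wide level left after normalization, with an SD of array medians of 0.110, would also move the panel together and stays open here. Among known regulatory links, the median correlation was 0.423 over 18 pairs such as nodal and Lefty, gcm and Fmo2, or tbr and SM50, and a random set of pairs reached that with a permutation p of 0.336, so these data give no sign that linked genes vary together more than other genes.

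Genes of 1 embryonic territory might vary together across crosses. Aboral ectoderm genes had a mean correlation of 0.576 (4 genes, permutation p = 0.0827), oral ectoderm genes 0.447 (12 genes, p = 0.146), endoderm genes 0.431 (13 genes, p = 0.178), non-skeletogenic mesoderm genes 0.330 (4 genes, p = 0.599) and skeletogenic mesenchyme genes 0.296 (25 genes, p = 0.913), each against 10000 random lists of the same size by permutation. None of the 5 passed 0.05, which by the rule fixed beforehand counts against the hypothesis. The skeletogenic and the non-skeletogenic mesoderm genes lay below the median and the mean (0.361 and 0.362) of random lists. With 4 genes, the non-skeletogenic value lay well inside the random lists and decides neither way. The skeletogenic list holds Alx1, ficolin, Ets1 and snail, only 0.07, 0.04, 0.88 and 0.39 log2 units above the negative controls in block 3. Whether such signal lowered its mean correlation was not tested, so the hypothesis stays open for this list.

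A wider spread among crosses at the highest temperature was also tested. The log2 ratio of the variance between crosses at 18C over that at 12C had a median of 0.03 over genes (value 0.0302, 95% bootstrap over crosses -0.511 to 0.596), and the interval leaves either direction open.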
